A study of Homo sapiens with 3 samples.

How the data were processed

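Total RNA of SK-HEP-1 cells was labelled with Cy3 and hybridised to 3 single-colour Agilent whole-genome expression arrays, 1 for each transfected plasmid (empty vector, insertion vector, deletion vector). The cells had been plated at 200000 per well and collected 24 h after transfection, per the labels' protocols. Arrays were scanned and spots quantified with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. The deposited scanner files give intensity per spot on a linear scale, and per the file headers the processed signal is background-subtracted and detrended within each array, with low spots replaced by a surrogate value and no scaling between arrays. They also give a p-value of each spot against its background, per the file headers, which was read but used in no result. The deposited series matrix holds log2 values of the same arrays. Each of its columns correlated with its own array's scanner values at r of 0.9999 or more over 20836 probes well above background on all 3 arrays, and differences between arrays correlated at 0.988 to 0.993, so its scale is log2, its genes are not centred and its direction is known. Its columns each have a median of 4.71, and 99.99% of their ranked values were equal within 0.01, which is what quantile normalization gives. The authors' normalization software is not given in the sources used here.

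Every array has 62976 spots, of which 58717 are non-control spots of 50599 probes; 902 probes were spotted 10 times. The median SD of log2 signal among such repeated spots was 0.048, 0.054 and 0.046 for the empty, insertion and deletion vectors. No non-control spot was saturated. The insertion-vector array had a higher negative-control signal (48.5, against 35.2 for the empty vector and 35.1 for the deletion vector), a lower slope of the spike-in curve (0.907 against 0.983 and 0.985) and a higher detection limit (2.03 against 1.55 and 1.40). Its negative-control and detection-limit metrics were out of the range set in the software, and those of the other 2 arrays were within it.

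The main values were log2 processed signals minus the array's 75th percentile over non-control spots (signals of 721.8, 702.8 and 879.4). Spots marked as outliers were left out (432, 513 and 480), and spots of 1 probe were averaged. Probes were named through their RefSeq accession in the RefSeq gene list of GRCh38.p14 (28174 probes), through a current symbol (2618) or an older symbol (620); 19187 kept the name of the file, giving 36400 genes, 21054 of them with a current symbol. Names, gene types and neighbouring genes were taken from that list. Probe positions are those of the array annotation on hg19. Per comparison, a gene's value was the mean of its probes well above background on both arrays. The lowest level of a probe well above background was -4.92, -4.10 and -5.04. A gene with probes well above background on only 1 array was given a bound, "at least N-fold", from the bright value against the higher of the dim value and that lowest level.

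With 1 array per group no test was run and no p-value was computed. A gene was counted as changed when its log2 difference was at least 1 in size (2-fold). The medians of 27 gene lists were set against 10000 random lists of the same size, matched on mean signal over the 3 arrays in 20 bins; a list stands apart when its percentile is at most 2.5 or at least 97.5, and lists with fewer than 5 measured genes have values only. This describes these arrays. The lists, the comparisons, the main setting and the rule for named genes were fixed before the data were examined. The rule names, per comparison, among genes with a symbol whose measured probes go the same way, the 8 highest and 8 lowest differences, then the 4 highest and 4 lowest not yet named among genes above the median signal (the brighter part), the 3 largest bounds in each direction, and up to 4 members with the largest difference in a list; examples were given for lists that stand apart. Genes with only a locus, transcript or probe name were counted and not named. Some genes that the rule takes are not reported here.

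Alternatives were quantile normalization, cyclic loess with 3 iterations, normexp background correction with an offset of 50 on mean and background signals, the deposited log2 values, no filter on dim probes, the brighter part of the genes, probes well above background on all 3 arrays, the brightest probe, outlier spots kept, and thresholds of 1.5-fold and 3-fold. A 75th percentile over detected probes and removal of the trend with probe GC content were added after seeing the data. For the deletion vector against the empty vector (18177 genes), arrays were simulated from the empty-vector array with the noise of repeated spots. All 50 genes raised and all 50 lowered by 1.5 were counted (100%), as were 0 of 17977 unchanged genes. Of the genes shifted by 0.5 in size, 0% were. That noise gave a difference an SD of 0.066, while the measured differences had an SD of 0.326 across genes. These results therefore follow from the small simulated noise. They do not show how often an unchanged gene passes 2-fold between separately prepared arrays. On the measured differences, 4.0% of 200 random lists of 20 genes stood apart, and 100% did when shifted by 0.3. These lists were drawn at random too, so the 4.0% does not cover lists whose members vary together. Overlap against the shared empty vector was simulated 1000 times with unchanged arrays. Computations used R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A planned analysis of genes with miR-3131 seed sites needs 3' untranslated region sequences, which were not used here.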

Results

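Gene expression was measured in SK-HEP-1 cells, a human liver cancer line, 24 h after transfection with 2.5 µg of 1 of 3 plasmids. The empty vector was pEGFP-N1, a plasmid that expresses a green fluorescent protein. The insertion vector carried a 366 bp fragment with the precursor of the microRNA miR-3131 and the insertion allele of an insertion/deletion polymorphism in it. The deletion vector carried the deletion allele of the same fragment. Each plasmid was represented by 1 single-colour array, so no difference below has a replicate check, no test was run, and the number of arrays limits the precision. Errors given below were computed for the difference of a gene between 2 arrays from the errors that the scanner software models per spot. They cover measurement noise only. Of 50599 non-control probes, 25383 (50.2%) were well above background on the empty-vector array, 25584 (50.6%) on the deletion-vector array and 21921 (43.3%) on the insertion-vector array. The insertion-vector array lay on a different slide and came from a different scan than the other 2 arrays. Slide and vector therefore cannot be told apart in both comparisons that use it, and the deletion vector against the empty vector is the only comparison within 1 slide. Differences also followed the GC content of the probes, with a Spearman rho across probes of -0.28 for the insertion vector and -0.35 for the deletion vector against the empty vector, and 0.06 between both miR-3131 vectors. Between these 2 vectors, probes with at least 60% GC still had a median difference of 0.302 (deletion minus insertion), against -0.03 for probes under 40%. With the position of the probe in its transcript, rho was 0.22 (insertion against empty), 0.225 (deletion against empty) and -0.08 (deletion against insertion). Levels are log2 signals relative to the array's 75th percentile.

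The transfected product itself was not measured, since no probe on the array is named for miR-3131 (0 probes). MIR3131 lies within the span of IHH, the Indian hedgehog gene, in the reference gene table. IHH was not well above background on any of the 3 arrays, with levels of -5.34 (empty vector), -6.21 (insertion vector) and -6.30 (deletion vector).

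The insertion vector was compared with the empty vector to ask which transcripts differed when the insertion allele was introduced. Interferon-response genes were lower on the insertion-vector array: all 34 measured members of this list lay below 0, with a median log2 difference of -0.81, and 10 were at least 2-fold lower. RSAD2, which encodes the antiviral protein viperin, was 2.86-fold lower (log2 difference -1.52, modelled error 0.20), with its probe on chromosome 2 at 7037200 to 7037259 (hg19). IFI27 was 2.89-fold lower, IFIT2 2.52-fold lower over 2 probes, and IFNL1, a type III interferon, 2.63-fold lower (modelled error 0.31). Genes of the cell division cycle were higher. The G2/M list had a median of 0.31 with 20 of 24 members above 0, and the S-phase list a median of 0.29 with 18 of 20 above 0. CDK1, the kinase that drives entry into mitosis, was 2.06-fold higher (log2 difference 1.04, modelled error 0.22, 2 probes), CENPE 1.79-fold, CCNA2 1.56-fold and the helicase subunit MCM6 1.54-fold higher.

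Other lists also stood apart from random lists of the same size and brightness on the insertion-vector array. NF-kB and inflammatory genes were lower, with a median of -0.27 and 19 of 26 members below 0. Among them the chemokines CXCL5 and CCL5 had log2 differences of -1.53 and -0.999, and IL6, the interleukin 6 gene, one of -0.80. All 36 ribosomal protein genes lay below 0, with a median of -0.32, though after quantile normalization the median was -0.07 and the list no longer stood apart (percentile 16.9). RPL14 had the largest difference in it, at -1.21; ribosomal protein genes have many near-identical pseudogenes, so their probes may also bind other transcripts. Replication-dependent histone genes had a median of -0.23, with 18 of 22 below 0, and H4C4 and H1-3 both had a log2 difference of -0.76. Genes of microRNA processing had a median of 0.18, with 12 of 18 members above 0. DROSHA and DICER1, the nucleases that cut microRNA precursors, had differences of 0.43 and 0.40. This list did not stand apart with normexp background correction, without the filter on dim probes or in the brighter part of the genes. The percentiles of these 7 lists among random lists were 0 for interferon, 0.1 for NF-kB, 0.06 for ribosomal proteins, 0.12 for histones, 97.8 for microRNA processing, and 99.99 for both S phase and G2/M. About 1.2 of the 24 lists with a percentile would stand apart by chance if the members of a list varied independently. The random lists draw each gene separately, so this number does not cover lists whose members vary together between arrays.

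**Figure D1:**
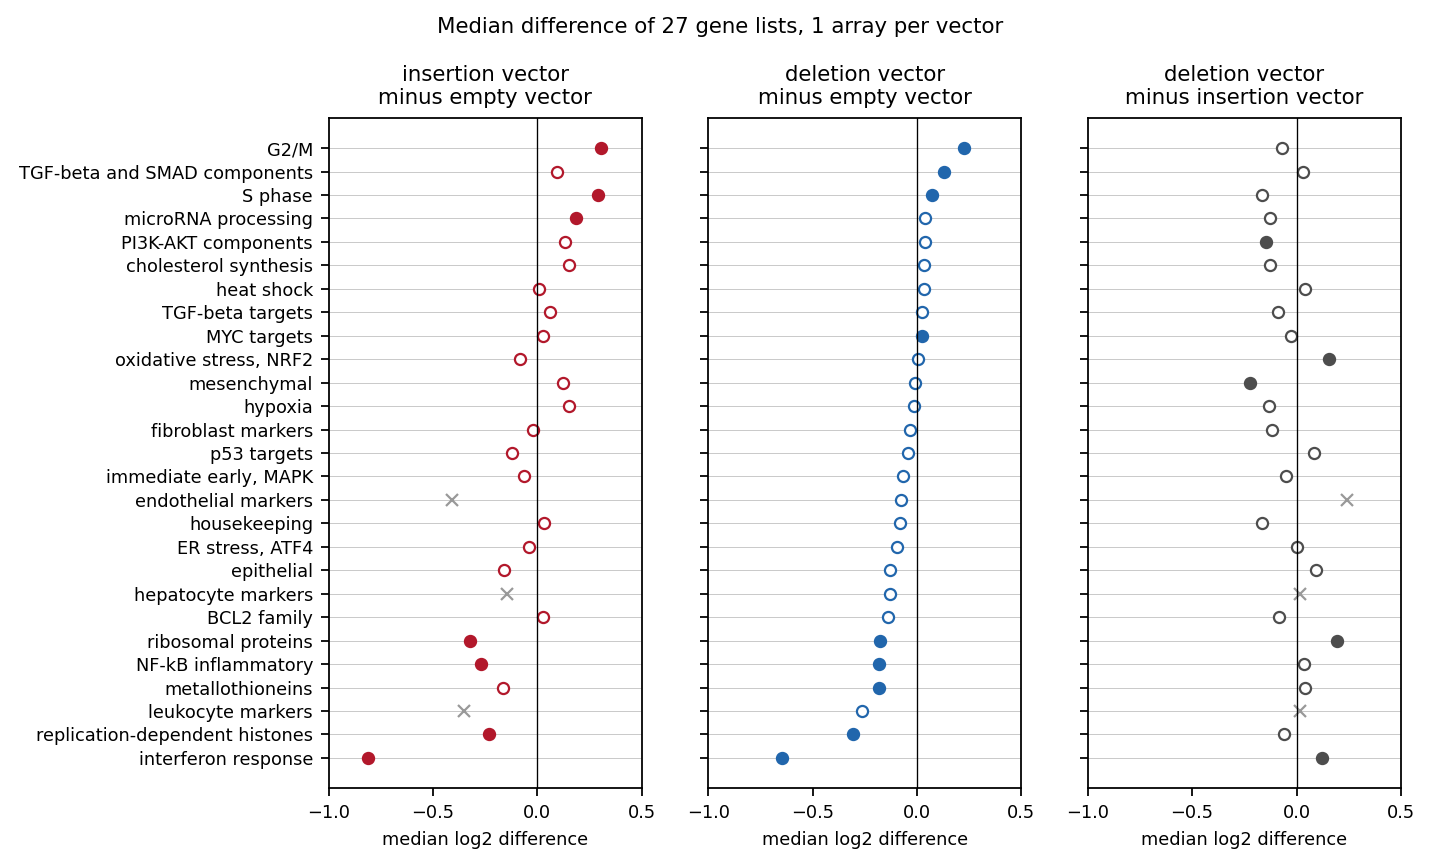
Median log2 difference of each of the 27 gene lists in the 3 comparisons, with 1 array per vector; filled circles stand apart from random lists, open circles do not, and grey crosses have fewer than 5 measured genes and no percentile. The interferon list lies lowest in both comparisons with the empty vector, at -0.81 and -0.65, while the ribosomal protein median in the middle panel (-0.18) becomes 0.01 after quantile normalization.

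Counted gene by gene, 969 of 15805 measured genes were at least 2-fold lower and 177 at least 2-fold higher on the insertion-vector array than on the empty-vector array, so that 84.6% of these genes were lower. Of these, 421 lower and 94 higher genes have a current symbol, against 13026 of the 15805 measured genes. Genes without a symbol thus made up most of the lower genes, but a smaller part of those measured. Among symbols whose probes all went the same way, LRRD1 was lowest, at 18.8-fold (log2 difference -4.23, modelled error 0.24, probe on chromosome 7 at 91774258 to 91774317, hg19). In all 3 comparisons, the genes taken from the highest and lowest differences had 1 measured probe each, apart from CHTOP. For 1 probe the same-way condition is met by itself, so no other probe checks these values. TUSC8 (-3.55), the readthrough locus LYNX1-SLURP2 (-3.38), PRSS36 (-3.25), C5orf58 (-3.15) and the zinc finger gene ZNF90 (-3.11) followed. PABPC3 (-3.18) and NACA4P (-3.01) are close copies of the expressed genes PABPC1 and NACA, so their probes may also bind those transcripts and their values are uncertain. In the brighter part of the genes, ELFN1 (-2.54) and LRRN2 (-2.51) were lower. The largest positive differences were in genes close to the detection limit on the empty-vector array. MYBPC3, the cardiac myosin-binding protein C gene, was 12.3-fold higher (log2 difference 3.63, modelled error 0.33), at a level of -4.73 on the empty-vector array. VPS13D (3.36), GPR132 (3.31), GCH1 (3.17), IFITM10 (3.15), SWSAP1 (3.03), ECSCR (2.97) and the olfactory receptor gene OR5J2 (2.92) were also higher. Brighter genes with higher signal were the deubiquitinase genes USP8 (1.40) and USP1 (0.94), the homeobox gene UNCX (1.04) and the kinetochore gene KNL1 (0.93). The UNCX probe has 91.7% GC, and differences between arrays followed probe GC content. Probes with at least 60% GC had a median of -0.527 in this comparison, so UNCX went against that trend.

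A further 4118 genes were well above background on only 1 of these 2 arrays, which gives bounds. By these bounds 753 genes were at least 2-fold higher and 487 at least 2-fold lower on the insertion-vector array. The lowest level of a probe well above background was -4.92 on the empty-vector array and -4.10 on the insertion-vector array. A gene therefore needed a brighter signal to count as lower than as higher, and the balance of these counts gives no direction. SYNPR, which encodes a synaptic vesicle protein, was at least 128-fold higher, PLPPR4 at least 34.4-fold and MUC22 at least 25.5-fold higher. RNF39 was at least 11.2-fold, SNORD105 at least 11.1-fold and PTOV1-AS1 at least 10.6-fold lower. The count of higher genes depended on dim probes: in the brighter part of the genes, 5 of 7902 were at least 2-fold higher and 335 lower. Different probes of a gene agreed weakly across genes (r = 0.24 over 3831 genes with 2 or more probes; genes are not independent replicates). For the deletion vector this r was 0.26 against the empty vector and 0.09 against the insertion vector.

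**Figure D2:**
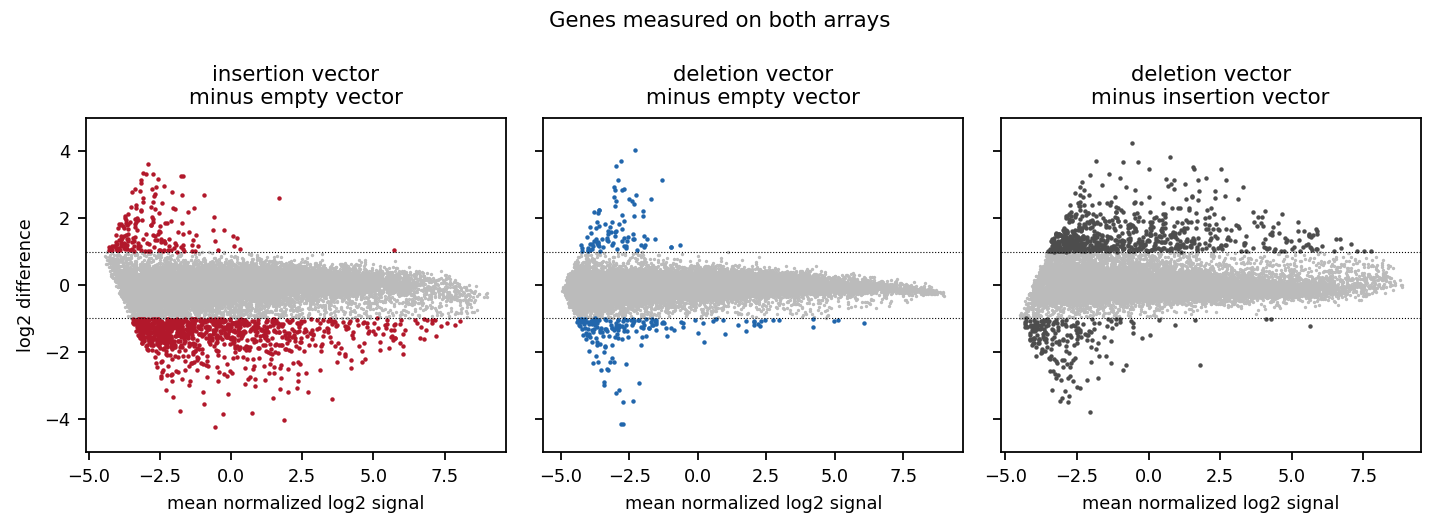
Log2 difference of each gene measured on both arrays against its mean normalized log2 signal, for the 3 comparisons; coloured points are at least 2-fold apart (dotted lines). The deletion vector and the empty vector, which share a slide, differ in 268 genes, against 1146 for the insertion vector and the empty vector.

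The deletion vector was compared with the empty vector to ask the same of the deletion allele, and both arrays lay on 1 slide. Interferon-response genes were again lower: all 35 measured members lay below 0, with a median log2 difference of -0.65, and 4 were at least 2-fold lower. These were IFNL1 (2.33-fold, log2 difference -1.22, modelled error 0.24), RSAD2 (2.24-fold), OAS1 (2.12-fold), which encodes a sensor of double-stranded RNA, and MX1 (2.06-fold, log2 difference -1.04, modelled error 0.20; probe on chromosome 21 at 42831014 to 42831073, hg19). The NF-kB list had a median of -0.18 with 21 of 26 members below 0. CCL5 had a difference of -0.87, the adhesion molecule gene ICAM1 one of -0.46 and IL6 one of -0.41. The G2/M list was higher, with a median of 0.22 and 21 of 24 members above 0. CDK1 (0.57), CENPE (0.52), TOP2A (0.48) and KIF11 (0.48) had the largest differences in it.

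Replication-dependent histone genes were lower with the deletion vector, with a median of -0.31 and 20 of 22 members below 0. H2AC11 (-0.88), H3C4 (-0.70), H3C2 (-0.66) and H1-4 (-0.65) were the furthest from 0. Ribosomal protein genes had a median of -0.18, with 34 of 36 below 0, but this median was 0.01 after quantile normalization and in the deposited processed values. The deposited values have nearly equal ranked values on all arrays, so they are no separate check of quantile normalization. Other lists that stood apart were S-phase genes (median 0.07), TGF-beta and SMAD components (0.13), MYC targets (0.03) and metallothioneins (-0.18, all 10 below 0). None of these 4 lists stood apart once the trend with probe GC content was removed, when their percentiles were 96.7, 89.5, 91.3 and 25.1. The percentiles before that were 98.2 for S phase, 98.2 for TGF-beta and SMAD components, 98.9 for MYC targets and 1.94 for metallothioneins. They were 0 for interferon and histones, 0.02 for ribosomal proteins, 0.05 for NF-kB and 100 for G2/M.

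**Figure D3:**
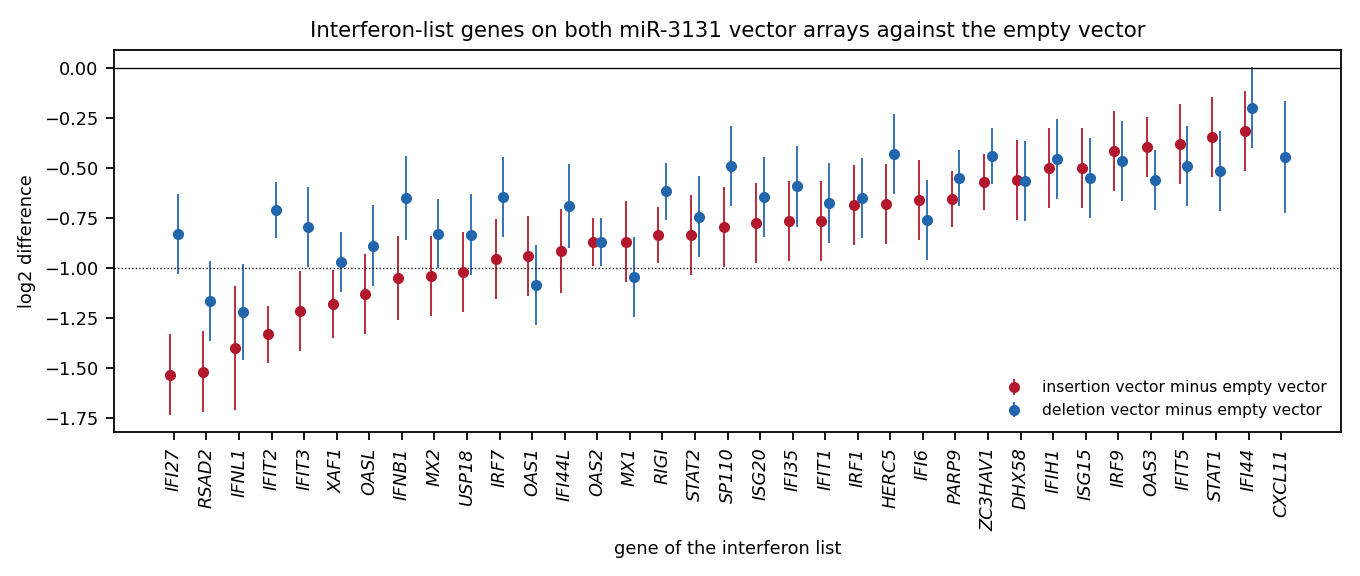
Log2 difference of each measured interferon-list gene for the insertion vector (red) and the deletion vector (blue) against the same empty-vector array; bars are the modelled error and the dotted line marks 2-fold. All points lie below 0, from -1.53 (IFI27, insertion vector) to -0.20 (IFI44, deletion vector).

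Between the deletion vector and the empty vector, 178 of 18177 measured genes were at least 2-fold lower and 90 at least 2-fold higher. RLBP1, a retinaldehyde-binding protein gene, was 17.9-fold lower (log2 difference -4.16, modelled error 0.34). LINC01341 (-3.50), SNORD105 (-3.46), the dynein heavy chain gene DNAH12 (-3.22), SCGB1B2P (-3.13), LINC03019 (-2.89), ASAP1-IT1 (-2.36) and the calcitonin gene CALCA (-2.33) were also lower. All of these were dim, with levels below -0.6 on the empty-vector array. On the deletion-vector array their levels ran from -4.98 (CALCA) to -3.78 (ASAP1-IT1), where the lowest level well above background was -5.04. Lower genes of the brighter part were CHTOP (-1.70, 2 probes), RNF222 (-1.48), CMPK2 (-1.43) and RMRP (-1.38), the RNA of the RNase MRP complex. PDZD7 was 16.3-fold higher (log2 difference 4.03, modelled error 0.30; probe on chromosome 10 at 102768513 to 102768572, hg19). NR1I3, the gene of the constitutive androstane receptor (3.69), SLC22A20P (3.54), the adhesion gene NECTIN1 (3.15), SNORD94 (2.83), CD244 (2.56) and NXNL1 (2.50) were higher too, as was a transcript known by a clone name only (2.70). On the empty-vector array PDZD7 (-4.31), NR1I3 (-4.66), SLC22A20P (-4.75) and SNORD94 (-4.19) were close to the lowest level well above background (-4.92). The others of these higher genes had levels there from -3.66 (NXNL1) to -2.87 (NECTIN1). No gene of the brighter part was at least 2-fold higher (0 of 9088), where 25 were lower. The 4 named there with the highest differences were FNIP2 (0.88), CKAP2L (0.85), DNAJB14 (0.80) and ZDHHC9 (0.76). Bounds put 356 genes at least 2-fold higher and 350 at least 2-fold lower. RPL34-DT was at least 40.6-fold, MMD2 at least 21.9-fold and TLR4, the lipopolysaccharide receptor gene, at least 20.9-fold higher. RNF39 was at least 21.7-fold, PTOV1-AS1 at least 20.4-fold and MYL11 at least 17.0-fold lower.

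The deletion vector was set against the insertion vector to compare both alleles directly, on 2 slides. Interferon genes were slightly higher with the deletion vector, with a median of 0.12 and 23 of 34 members above 0. None of them reached 2-fold, and IFI27 (0.70) and IFIT2 (0.62) differed most. Ribosomal protein genes had a median of 0.19, with 33 of 36 above 0, against 0.02 (percentile 96.9) in the deposited processed values; RPL14 was 2.03-fold and RPS27A 1.73-fold higher. Mesenchymal genes were lower, with a median of -0.22 and 12 of 17 below 0. ITGB1 (-0.58), MMP14 (-0.50) and SNAI1 (-0.48) were lower in it, while VIM, the vimentin gene, had a difference of 0.54. PI3K-AKT components had a median of -0.15 with 19 of 26 below 0, where TSC2 had a difference of -0.76 and EGFR one of 0.73. Oxidative stress genes of the NRF2 response had a median of 0.16 with 8 of 14 above 0, and OSGIN1 (0.55) and HMOX1 (-0.52) lay furthest out on either side. The percentiles were 99.9 for interferon, 99.97 for ribosomal proteins, 0.15 for mesenchymal genes, 1.45 for PI3K-AKT components and 98.5 for the NRF2 list. After removal of the GC trend the PI3K-AKT percentile was 6.21. In the brighter part of the genes, neither the mesenchymal, the PI3K-AKT nor the NRF2 list stood apart, and the NRF2 median was -0.07.

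Between these 2 arrays, 692 of 15821 measured genes were at least 2-fold higher with the deletion vector and 203 at least 2-fold lower, so that 22.7% were lower. Of these, 299 higher and 115 lower genes have a current symbol, against 13031 of the 15821 measured genes. Without the filter on dim probes the balance turned, with 2455 higher and 4163 lower genes (62.9% lower). Of the 24 genes that the naming rule takes from the highest and lowest differences here, 15 were also taken for the insertion vector against the empty vector. LRRD1 was 18.8-fold higher with the deletion vector (log2 difference 4.23, modelled error 0.24), followed by TUSC8 (3.68), LYNX1-SLURP2 (3.51), PRSS36 (3.46), NECTIN1 (3.33), PABPC3 (3.13) and ZNF90 (3.13). Apart from NECTIN1, these genes had similar levels on the deletion-vector and empty-vector arrays and were low on the insertion-vector array. LRRD1 had levels of 1.53, 1.53 and -2.70 on these arrays, and TUSC8 of 0.96, 0.84 and -2.72. Their differences thus repeat the low insertion-vector readings given above. The difference of LYNX1-SLURP2 turned to -0.04 without the filter on dim probes. In the brighter part NACA4P (3.12), ELFN1 (2.58) and the transcription factor genes BHLHE23 (2.54) and LHX3 (2.30) were higher. The probes of BHLHE23 (75% GC) and LHX3 (65% GC) are GC-rich, and probes with at least 60% GC had a median of 0.302 here. GPR132 was 11.3-fold lower (log2 difference -3.50, modelled error 0.36). MYO15B (-3.47), MYBPC3 (-3.32), the calcium-binding protein gene CABP4 (-3.18), ECSCR (-3.07), GCH1 (-3.05), LINC00239 (-2.86) and SWSAP1 (-2.84) were lower as well. GPR132 and these genes were dim on the deletion-vector array, with levels there from -4.82 (MYO15B) to -3.94 (ECSCR). UNCX (-1.23), LINC02245 (-1.20), RMRP (-1.06) and TINAGL1 (-1.02) were the lower genes named from the brighter part, where 7 of 7910 genes were at least 2-fold lower and 240 higher. The probes of UNCX (91.7% GC) and TINAGL1 (65% GC) are GC-rich too, though the median of GC-rich probes went the other way. Bounds put 414 genes at least 2-fold higher and 794 lower, led by RPL34-DT (at least 23.0-fold), PDZD7 (14.1-fold) and CD244 (12.8-fold) on the higher side and SYNPR (140-fold), PLPPR4 (37.6-fold) and MUC22 (27.9-fold) on the lower side. The balance of these 2 counts gives no direction. With lowest levels of -4.10 on the insertion-vector array and -5.04 on the deletion-vector array, a gene needed a brighter signal to count as higher. The bounds of SYNPR, PLPPR4 and MUC22 repeat the bright insertion-vector readings behind their bounds given above.

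Against the shared empty vector, 39 genes differed at least 2-fold the same way with both miR-3131 vectors, of 15750 genes measured in both comparisons. Of these, 38 were lower with both vectors and 1 was higher with both, while 2 genes went opposite ways. The interferon-list genes RSAD2 and IFNL1 were among the 38, as were CMPK2, RNF222, DNAH12 and ASAP1-IT1, named above. Independent lists of these sizes would share 5.41 lower and 0.34 higher genes. Simulated unchanged arrays that share a control gave means of 163 lower and 163 higher genes with the spread between the deletion and insertion arrays. With the spread between the deletion and empty arrays they gave means of 10.5 lower and 10.5 higher genes, and at most 24 of either. Across genes, which are not independent replicates, the differences of both vectors correlated with r = 0.43. Both simulations gave 0.50, but each gave all arrays the same spread, which sets this value whatever the data. The measured differences from the empty vector had unequal SDs, 0.547 for the insertion vector and 0.326 for the deletion vector. The simulated 0.50 is therefore no reference for the observed r. The simulations also treat both directions alike, so they cannot show why 38 shared genes were lower and 1 higher. The covariance of the differences of both vectors was 0.06, against simulated values of 0.12 and 0.04. The simulated spreads include any real differences between the arrays they were taken from, and the control is 1 array that cannot be split, so part or all of the overlap may come from the shared control.

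In both comparisons with the empty vector, the lists not described above did not stand apart from random lists. After removal of the GC trend, mesenchymal genes did for the insertion vector (percentile 98.6), and cholesterol synthesis genes (99.7) and leukocyte markers (1.72) did for the deletion vector. For the insertion vector against the empty vector, their medians were 0.10 for TGF-beta and SMAD components, 0.06 for TGF-beta targets, 0.03 for MYC targets, -0.12 for p53 targets, 0.03 for the BCL2 family, -0.04 for ER stress and 0.01 for heat shock. They were -0.06 for immediate early genes, 0.13 for PI3K-AKT components, 0.15 for hypoxia, 0.15 for cholesterol synthesis, -0.08 for the NRF2 list, -0.16 for metallothioneins, 0.12 for mesenchymal genes, -0.16 for epithelial genes, -0.02 for fibroblast markers and 0.03 for housekeeping genes. With the deletion vector against the empty vector, the medians were 0.03 for TGF-beta targets, -0.05 for p53 targets (7 of 20 above 0), -0.14 for the BCL2 family, -0.10 for ER stress, 0.03 for heat shock, -0.06 for immediate early genes, 0.04 for PI3K-AKT components, -0.01 for hypoxia and 0.04 for cholesterol synthesis. Those of the NRF2 list (0.01), mesenchymal genes (-0.01), epithelial genes (-0.13), microRNA processing (0.04), fibroblast markers (-0.03) and housekeeping genes (-0.08) were likewise within the range of random lists. Cell-type markers were sparsely measured on the deletion-vector and empty-vector arrays: 6 of 24 hepatocyte, 8 of 19 endothelial, 9 of 20 leukocyte and 9 of 14 fibroblast markers. Their medians were -0.13 for hepatocyte, -0.07 for endothelial and -0.26 for leukocyte markers. On the insertion-vector and empty-vector arrays only 4 genes of each of these 3 lists were measured, with medians of -0.14, -0.41 and -0.35 and no percentile.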

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

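Removal of the GC trend and the 75th percentile over detected probes were chosen after the results were seen; both left all 6 counts of changed genes and the overlap within 1.5 times. No paired analysis was possible because each group has 1 array and no test was run. The analysis of seed-site genes and its alternatives were not run. Signal over background limits the counts, and where counts moved the cause was not tested, apart from thresholds and filters that change which genes are counted. Counts follow as higher and lower, in the order insertion against empty, deletion against empty, deletion against insertion. Normexp gave 64 and 602, 30 and 44, 412 and 68. Without a filter on dim probes they were 2311 and 3102, 1142 and 1919, 2455 and 4163; in the brighter part 5 and 335, 0 and 25, 240 and 7. At 1.5-fold they were 621 and 2020, 269 and 761, 1531 and 534, and at 3-fold 75 and 309, 38 and 34, 228 and 89. Cyclic loess gave 269 higher genes for the insertion vector against the empty vector. Probes well above background on all 3 arrays gave 31 higher and 85 lower genes for the deletion vector against the empty vector. The 39 genes shared by both vectors became 14 with normexp, 982 without the filter and 8 in the brighter part. The other 50 values of counts lay within 1.5 times.

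Among lists that stood apart, 4 medians changed sign: ribosomal proteins, deletion against empty (0.008 after quantile normalization, 0.014 with the deposited values), TGF-beta and SMAD components, deletion against empty (-0.047 without the filter), and the NRF2 list, deletion against insertion (-0.07 in the brighter part). The interferon, NF-kB, G2/M and histone lists stood apart from random lists the same way under all 11 alternatives, with both vectors against the empty vector; for interferon the medians ranged from -0.93 to -0.76 (insertion) and from -0.65 to -0.62 (deletion). Among named genes, 1223 of 1638 values moved by less than the SD of a difference between repeated spots, and among those at least 2-fold apart only LYNX1-SLURP2 changed sign under an alternative, to -0.036 without the filter for the deletion vector against the insertion vector.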

Other observations

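Short non-coding RNAs, mostly small nucleolar RNAs, are a group that the lists above do not hold. On the deletion-vector array 220 of 239 measured members were lower than on the empty-vector array, with a median log2 difference of -0.44, and 20 were at least 2-fold lower. Their median was -0.13 on the insertion-vector array, with 155 of 215 below 0. Deletion against insertion, it was -0.31. The direction held under each scaling tried (deletion against empty: -0.42 after quantile normalization, -0.27 with normexp, -0.35 after removal of the GC trend). Long non-coding RNAs had medians of -0.12 (insertion against empty, 482 genes) and -0.08 (deletion against empty, 636 genes). These groups were chosen after the data were seen.

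Of the tests below, those of signal compression, of genes not typed as pseudogenes, of the insertion allele, of slide and scan, of a high empty-vector array and of brightness-dependent scaling were chosen after the results were seen, and those of GC content use a correction that was added after seeing the data.

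The insertion-vector array held more genes at least 2-fold lower than the deletion-vector array, against the same empty vector (969 and 178). Removing the trend with probe GC content gave 853 such genes, and cyclic loess, which removes brightness-dependent trends, gave 941, which argues against either trend as the whole cause. Normexp background correction gave 602 such genes with the insertion vector and 44 with the deletion vector. The counts thus depended on how background was handled, while the excess with the insertion vector remained. A part of the brighter background in it stays open. Pseudogenes were lower as a set on the insertion-vector array (median -0.22, percentile 0 among random lists, 33 genes 2-fold lower); deletion against insertion their median was 0.12 at percentile 100. Weaker cross-hybridisation of their probes was predicted to lower them on that array alone, but on the deletion-vector array (median -0.07, percentile 3.61) their percentile was at most 1.1 under 5 of 6 alternatives. Long non-coding RNAs went a similar way, with percentiles of 0.03 (insertion) and 6.99 (deletion) and 45 of 482 genes 2-fold lower on the insertion-vector array. Weaker cross-hybridisation therefore stays open for pseudogenes, and also for the other 936 genes, since retrocopies and unnamed transcripts were not typed here. Of the 969 lower genes, 421 have a current symbol, against 13026 of 15805 measured genes. The insertion allele also stays open and cannot be told apart from the slide, which held 0 other arrays.

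Interferon genes were lower with both miR-3131 vectors than with the empty vector. For the deletion vector, a difference between slides or scans is argued against by the list's percentile of 0 against the empty vector, within 1 slide. Removing the GC trend also left that percentile at 0 (median -0.64 against -0.65). For the insertion vector (median -0.81), a part of the slide or scan cannot be told apart from the vector. What stays open is whether the empty-vector array was high, from its transfection or its culture, or the miR-3131 vectors low: the series has 1 empty-vector array, and these cannot be told apart. A hypothesis that the miR-3131 fragment lowers the interferon response to a transfected plasmid, whatever the allele, was not tested for want of replicate arrays.

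Ribosomal protein and histone genes, both short transcripts, were lower with both vectors than with the empty vector. Among random lists matched on brightness and on probe position in the transcript, the percentile of these 58 genes stayed at 0.06 (insertion) and 0 (deletion), and it was 0 after removal of the GC trend (deletion), which argues against probe position and, for the deletion vector, probe GC content as the whole cause; transcript length itself was not measured, and the short non-coding RNAs were lower too. For the ribosomal protein genes with the deletion vector, the percentile was 84.1 after quantile normalization and 3.33 after cyclic loess, as brightness-dependent scaling predicts. These genes are very bright (RPL19 had a level of 8.79 on the empty-vector array). Quantile normalization makes ranked values equal between arrays, so it would also reduce a real joint fall of such genes. It cannot decide between the 2, and brightness-dependent scaling stays open. With the insertion vector such scaling stays open too, since the percentile of these genes was 16.9 after quantile normalization but 0.12 after cyclic loess (median -0.39). For the histone genes with the deletion vector the percentile after quantile normalization was 0, which argues against it, and an effect of the vectors on histone transcripts stays open and untested.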
